A study of Mus musculus with 6 samples.

How the data were processed

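Polyadenylated or total transcripts are not distinguished by the labels, which state only that total RNA was extracted with Trizol and made into libraries by standard Illumina protocols. The 6 libraries, 3 of C2C12 myoblasts with GFP and 3 with ChREBP-beta overexpression, were grouped by their titles. How the cells were made to overexpress the factor is not given in the sources used here.

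The values are estimated counts per gene symbol, deposited by the authors as a table of the whole series with a column per library, not normalized, and 7.74% of them are not whole numbers (compared with their rounded values). Per the submitters' processing notes, the tools were fastp, Bowtie2 2.0.0.5 and TopHat2 2.0.0, and the build named is GRCg6a, a chicken assembly. The symbols in the table are those of mouse genes. The mouse build, the gene annotation, the counting tool and the use of strand are not given in the sources used here. Values that are not whole mean that some reads were divided between genes, so genes with near-identical copies are less certain: 2055 of the genes tested (16.9%) held such split reads in at least 1 library. Overlapping and antisense genes cannot be told apart without knowing the strand setting.

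The table has 22298 rows and 22272 distinct symbols. Rows of the 24 symbols that occur more than once were summed, and the sums were rounded to whole counts. Genes were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr with its defaults (minimum count 10, minimum total 15) kept 12166 genes, library sizes were scaled by TMM, and glmQLFit and glmQLFTest compared the groups without further terms, two-sided, with Benjamini-Hochberg adjustment and calls at an adjusted p under 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of the F statistic. CPM values are scaled by the TMM factors, except sums over the lung, liver and blood lists, which are of all counts. The common biological coefficient of variation was 3.44%. A fold against a group with no count was computed against a floor of 3 counts over the group, and a ratio with 1 count has an exact 95% counting interval. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Gene locations are from GENCODE M21 (GRCm38), matched by symbol, which may not be the build the authors used.

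The main test, its alternatives, 18 gene lists, 5 cell type marker lists and the rule for named genes were fixed before the data were examined. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 on log2 CPM, two-sided, adjusted over the 18 lists. Named genes are Mlxipl, the 8 genes with the largest rise and the 8 with the largest fall among called genes with a mean CPM of at least 1 in the higher group and separated groups (symbols that are only Gm numbers, Rik names or identifiers are not named), the up to 3 members of each list with the smallest adjusted p, and the up to 2 members of each marker list with the highest mean CPM. Some genes that the rule picks are left out of the text. Other genes named in the text were picked as examples after their values were seen. Lists of circadian clock, insulin-like growth factor, semaphorin, Wnt, YAP and TEAD target, neuromuscular junction, lung, liver and blood genes were written after the data were seen.

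Libraries of a group were compared pairwise by a chi-square test of counts. The chi-square per degree of freedom lay between 2.17 and 3.98, above the sampling noise expected of a library deposited again, so all 6 were kept as separate samples. The deposited counts per library ran from 17600238 to 19163834, with libraries of both groups across that range. A gene with a mean CPM of 1 thus has 18.3 counts per library and a relative counting error of 23.4%.

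The edgeR procedure was tested on counts simulated from the real genes and libraries of this comparison (12062 genes passing the filter). It called 55.1% of genes changed 1.25-fold, 85.7% at 1.5-fold, 93.9% at 2-fold and 100% at 4-fold, and 12 of its 175 calls (6.86%) were false. Only 48 or 49 genes were changed at each fold, a far smaller share than the 58.7% called in the data. The rates in the real comparison may thus differ. On simulated data camera recovered a list shifted 1.5-fold and called 0 of 18 random lists. The simulated genes varied independently of each other, so this does not test how correlation between genes affects the list calls.

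The alternatives were RLE, upper-quartile and library-size scaling, no filter and a mean CPM of at least 5, DESeq2 1.42.0, limma-voom, the replicate number as a block, scaling without Mlxipl and the 10 most abundant genes, each library left out in turn, a 2-fold minimum, and for lists camera with an estimated correlation and fry. Added after seeing the data were a fit without genes carried by lung, liver or blood RNA (57 symbols, of which 47 were tested), offsets per library for transcript length and GC content (values for 99.0% of the tested genes), and lists without Mlxipl. Alternatives planned for normalized values were not needed, since the values are counts.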

Results

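RNA was sequenced from 6 samples of undifferentiated C2C12 cells, a mouse myoblast line that divides as muscle precursors and forms muscle fibres when serum is withdrawn. In 3 samples the cells carried green fluorescent protein (GFP) as the control, and in 3 samples they overexpressed ChREBP-beta. ChREBP-beta is the short, highly active isoform of the carbohydrate response element binding protein, a glucose-responsive transcription factor encoded by Mlxipl that drives genes of glycolysis and fat synthesis together with its partner Mlx. All samples were taken at day 0 of differentiation. The series concerns skeletal muscle ChREBP and fat within muscle, and the comparison here asks which transcripts differed in myoblasts that overexpressed the factor. The deposited gene counts summed to 18843244, 17850757 and 17600238 in GFP replicates 1 to 3 and to 18567502, 19163834 and 17665571 in ChREBP-beta replicates 1 to 3. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

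Mlxipl (ENSMUSG00000005373.13; chromosome 5, 135089890 to 135138382, plus strand, GRCm38) was read at 0.599 ± 0.111 CPM (counts scaled by library size; SD, n = 3) with GFP and at 219 ± 3.85 CPM (SD, n = 3) with ChREBP-beta. The log2 fold change was 8.50 (SE 0.080, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.18e-28), with all 3 ChREBP-beta libraries above all 3 GFP libraries. This was the smallest p of the 12166 genes tested, and it fits the group labels of all 6 libraries. Counts at the gene do not separate the introduced sequence from the cell's own transcript, nor the beta isoform from the full-length form. The other members of the MYC-MAX-MLX list changed less than Mlxipl. The largest of these changes was in Mycl, 23.5-fold lower at low counts (80 over the GFP and 3 over the ChREBP-beta libraries), and Mxd1 was 2.37-fold lower. Myc, a growth-promoting transcription factor, rose 2.12-fold and its partner Max 1.33-fold, while Mlx, whose counts include reads split between genes, was 1.19-fold lower and Mlxip, which encodes the ChREBP paralog MondoA, 1.30-fold lower. Of the 12 tested members of that list, 7 were higher, 4 were lower and 1 was not called (11 changed when adjusted over the list alone), and the list as a whole was not called (camera adjusted p = 0.240).

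The expression of 3584 genes was higher and of 3561 genes lower with ChREBP-beta, together 58.7% of the genes tested. Most differences were small: 4733 of the 7145 called genes changed by less than 1.5-fold. At least 2-fold changes were counted for 494 genes that rose and 903 that fell, or 11.5% of those tested. All libraries of one group lay above all of the other for 63.2% of the tested genes, where chance gives 10%.

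The largest rises, by the naming rule, were in genes that GFP libraries hardly read. Wnt7a, a Wnt ligand, had no count in the GFP libraries and 9.03 CPM with ChREBP-beta, at least 166-fold higher against a floor of 3 counts over the group. By the same floor, Rspo4, a secreted enhancer of Wnt signalling, was at least 77.2-fold higher, Teddm3 at least 60.7-fold, the immune receptor gene Cd244a at least 38.5-fold, Npas2, a paralog of the circadian factor Clock, at least 37.8-fold and the neural transcription factor gene Sox1 at least 37.4-fold. Cck, which encodes the peptide hormone cholecystokinin, rose from 0.252 ± 0.103 to 106 ± 4.11 CPM (SD, n = 3; edgeR adjusted p = 7.31e-26). The largest falls included muscle genes. Myog, the transcription factor that commits myoblasts to differentiation, had 118 counts over the GFP libraries and none with ChREBP-beta, at least 38.9-fold lower. Chrnd, the delta subunit of the muscle acetylcholine receptor, was at least 27.0-fold lower, Rasgrf1, an activator of Ras, at least 21.7-fold and Fgfr4, a growth factor receptor gene, at least 20.1-fold. Car3, the carbonic anhydrase abundant in muscle, fell 150-fold, from 139 ± 6.47 to 0.922 ± 0.417 CPM (SD, n = 3), and Col14a1, a collagen gene, fell 115-fold (edgeR adjusted p = 1.62e-25 and 1.88e-21). Mchr1 and Zim1 had 1 count each with ChREBP-beta, against 154 and 135 with GFP. The ratio was 152 for Mchr1 (95% counting interval 26.9 to 6049) and 133 for Zim1 (23.5 to 5308).

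**Figure D1:**
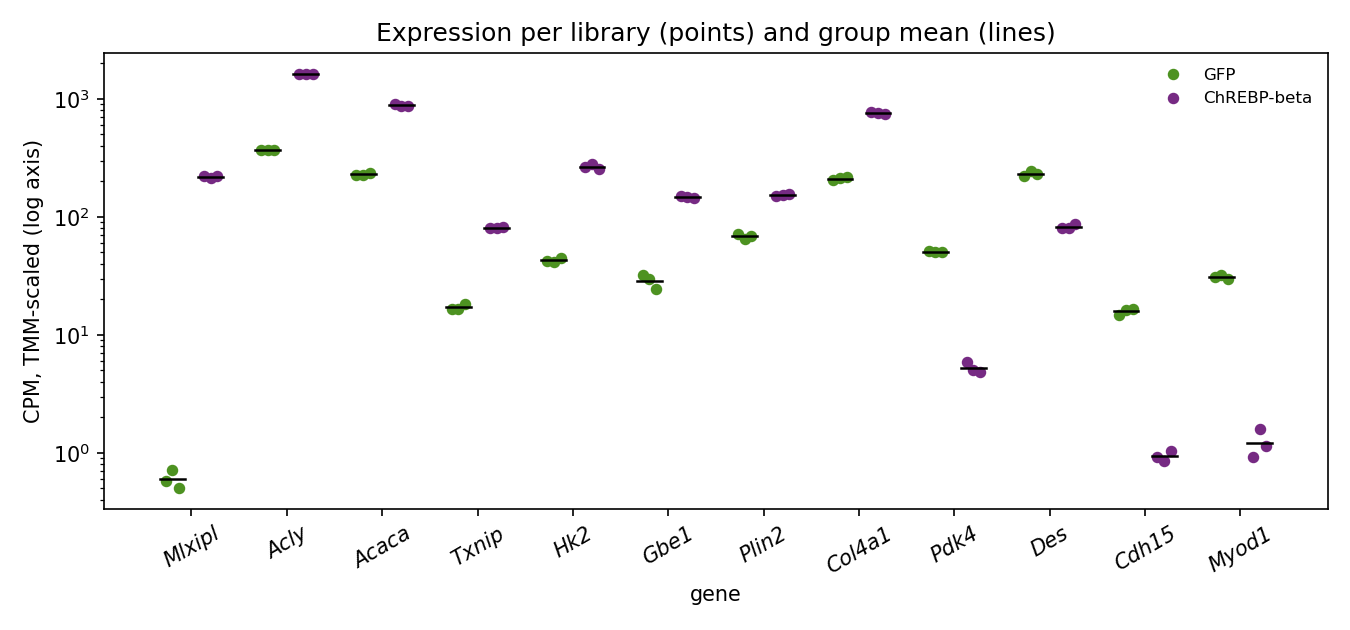
Expression of 12 genes in each library, in CPM on a log axis, with points for the 3 GFP (green) and 3 ChREBP-beta (purple) libraries and black lines for group means. Mlxipl stood at 0.599 CPM with GFP and 219 CPM with ChREBP-beta on average, Acly at 369 and 1624 CPM, and Myod1 at 30.8 and 1.23 CPM.

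Known ChREBP target genes rose as a group. Of the 17 tested members, 11 were higher, 4 lower and 2 not called (15 changed when adjusted over the list alone), and the median log2 fold change was 1.38 (camera adjusted p = 0.0015, or adjusted p = 0.248 with an estimated correlation). Acly, which makes cytosolic acetyl-CoA for fat synthesis, rose 4.40-fold from 369 ± 3.02 to 1624 ± 6.79 CPM (SD, n = 3), and Acaca, the acetyl-CoA carboxylase of fat synthesis, rose 3.84-fold (edgeR adjusted p = 1.07e-26 and 3.09e-25). Txnip, a glucose-induced inhibitor of glucose uptake, rose 4.71-fold, Klf10 3.87-fold, Rgs16 7.35-fold and Bhlhe40 2.61-fold. Other targets fell: Gpd1, glycerol-3-phosphate dehydrogenase, was 4.30-fold lower, the fructokinase gene Khk 1.64-fold, Acacb 1.75-fold. Scd1, the fatty acid desaturase whose counts include split reads, fell by 0.26 on the log2 scale. The list holds Mlxipl itself. Without it, a choice made after seeing the data, the median was 0.91 (camera adjusted p = 0.00609). The liver targets Pklr, G6pc, Slc2a2 and Gckr had too few counts to be tested.

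The wider fatty acid synthesis list was not called against the other genes by camera. It had 8 members higher, 7 lower and 4 not called (15 changed when adjusted over the list alone; median log2 fold change 0.02, camera adjusted p = 0.467). Besides Acly and Acaca, Elovl5 and Fasn, the fatty acid synthase gene, rose 1.36-fold and 1.35-fold, whereas Acsl3, which activates fatty acids, was 1.40-fold lower (edgeR adjusted p = 2.47e-12) and Acss2 1.36-fold lower. Triglyceride and lipid droplet genes had 12 members higher, 5 lower and 7 not called (17 changed when adjusted over the list alone), with a median of 0.23 (camera adjusted p = 0.103). Plin2, a coat protein of lipid droplets, rose 2.23-fold and G0s2, an inhibitor of triglyceride breakdown, 5.40-fold (edgeR adjusted p = 7.15e-18 and 4.63e-15). Plin4 fell 2.53-fold and Dgat2, an enzyme of the last step of triglyceride synthesis, 1.78-fold. Without GFP replicate 1, the triglyceride list was called higher (camera adjusted p = 0.0435). Of 11 tested adipocyte markers, 6 were higher, 3 lower and 2 not called (9 changed when adjusted over the list alone; median 0.75, camera adjusted p = 0.101). Lpl, lipoprotein lipase, rose 3.64-fold, Klf5 2.22-fold, Ebf1 2.05-fold and Cebpb 1.89-fold, while Zfp423, a marker of adipocyte precursors, was 11.7-fold lower. Pparg, the adipocyte master regulator, stood at 10.7 CPM with GFP and 9.28 CPM with ChREBP-beta (edgeR adjusted p = 0.145). Adipoq, Plin1, Cidec, Lep and Cfd, genes of mature adipocytes, had too few counts to be tested.

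Most glucose-handling genes changed, in both directions. Hk2, the inducible hexokinase, rose 6.25-fold from 42.7 to 267 CPM, Pfkfb3, which makes the activator of phosphofructokinase, rose 3.06-fold and Pfkl, the liver-type phosphofructokinase, 1.56-fold (edgeR adjusted p = 1.05e-24, 3.25e-17 and 1.68e-13). In the glycolysis list 14 of 24 tested members were higher, 7 lower and 3 not called (21 changed when adjusted over the list alone), and the list was not called (median 0.13, camera adjusted p = 0.112). Among its lower members were Slc2a4, the insulin-responsive glucose transporter, 6.48-fold lower at under 1 CPM, and Ldhb, 5.10-fold lower. In the pentose phosphate pathway 5 of 10 members were higher, none lower and 5 not called (5 changed when adjusted over the list alone). Tkt, transketolase, rose 2.65-fold, Rpia 1.51-fold and Pgd 1.29-fold (edgeR adjusted p = 8.09e-21, 1.54e-08 and 2.96e-10), while G6pdx, which opens the pathway, stood at 180 and 186 CPM (edgeR adjusted p = 0.229). The pathway was called higher (median 0.17, camera adjusted p = 0.0254), but not without GFP replicate 3 (camera adjusted p = 0.0607) and with adjusted p = 0.482 under an estimated correlation. Glycogen genes split, with 5 higher, 6 lower and 3 not called (12 changed when adjusted over the list alone). Ppp1r3b, which targets protein phosphatase 1 to glycogen, rose 15.9-fold, Gbe1, the glycogen branching enzyme, 5.11-fold and Ppp1r3c 5.08-fold, while Phkb, a subunit of phosphorylase kinase, fell 1.37-fold. The glycogen list was not called, its median of -0.14 and its mean of 0.46 differed in sign, and camera placed it on the higher side (adjusted p = 0.984).

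Genes of fatty acid oxidation were lower. Of 24 tested members, 17 were lower, 2 higher and 5 not called (21 changed when adjusted over the list alone), with a median of -0.27 (camera adjusted p = 3.90e-04, or adjusted p = 0.122 with an estimated correlation). Pdk4, the kinase that shuts off pyruvate oxidation, fell 9.62-fold from 50.7 ± 0.534 to 5.26 ± 0.541 CPM (SD, n = 3), Acadm, medium-chain acyl-CoA dehydrogenase, fell from 138 to 68.8 CPM and Ucp2, a mitochondrial carrier whose counts in 1 library include split reads, fell 2.39-fold (edgeR adjusted p = 9.27e-21, 2.46e-16 and 3.23e-15). Ppard, a nuclear receptor that promotes fat oxidation, rose 1.66-fold. Oxidative phosphorylation genes fell by small steps: 27 of 35 were lower, 1 (Cycs) was higher and 7 were not called (28 changed when adjusted over the list alone). Their median was -0.19 (camera adjusted p = 3.90e-04, or adjusted p = 0.248 with an estimated correlation). Atp5b, a subunit of ATP synthase, was 1.18-fold lower and Ndufs1 1.18-fold (edgeR adjusted p = 2.72e-08 and 1.79e-06). The share of counts at mitochondrially encoded genes was 9.76% ± 0.397 (SD, n = 3) with GFP and 8.34% ± 0.242 (SD, n = 3) with ChREBP-beta (two-sided exact permutation test, p = 0.1, the smallest that 3 against 3 allows).

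Myogenic transcription factors and muscle structural genes were markedly lower. Myod1, the transcription factor that sets muscle identity, fell 24.9-fold from 30.8 ± 1.21 to 1.23 ± 0.340 CPM (SD, n = 3), Cdh15, the muscle cadherin, fell 16.8-fold and Pax7, the satellite cell factor, 21.6-fold (edgeR adjusted p = 1.93e-19, 1.40e-16 and 4.76e-07). Id3, an inhibitor of myogenic factors, fell 2.15-fold, Myf5 2.86-fold and the integrin gene Itga7 2.07-fold, while Mef2d rose 1.65-fold. Among myogenic regulators 10 of 13 tested members were lower, 2 higher and 1 not called (12 changed when adjusted over the list alone), with a median of -1.05, which was the same with Myog at its bound (camera adjusted p = 5.70e-04, or adjusted p = 0.140 with an estimated correlation). Of 17 tested sarcomere and differentiated muscle genes, 13 were lower, 1 higher and 3 not called (14 changed when adjusted over the list alone), with a median of -2.38 (camera adjusted p = 4.17e-04, or adjusted p = 0.122 with an estimated correlation). Des, the muscle intermediate filament desmin, fell 2.82-fold from 232 ± 11.6 to 82.5 ± 3.69 CPM (SD, n = 3) and Actn3 fell 9.43-fold (edgeR adjusted p = 4.15e-20 and 7.37e-16). The giant sarcomere protein gene Ttn fell 17.4-fold and the embryonic myosin gene Myh3 3.25-fold. Tnnt2, cardiac troponin T, was the member that rose, by 4.30-fold (edgeR adjusted p = 3.91e-19). Most sarcomere genes had low counts in these undifferentiated cells, and under a filter at a mean CPM of at least 5 the list was not called (camera adjusted p = 0.0629), though its median was still -1.51.

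Extracellular matrix and contractile fibroblast genes were higher as a group. Of 29 tested members, 22 rose, 5 fell and 2 were not called (27 changed when adjusted over the list alone), with a median of 0.42 (camera adjusted p = 8.28e-05, or adjusted p = 0.482 with an estimated correlation). Col4a1, a basement membrane collagen, rose 3.62-fold from 211 ± 5.31 to 763 ± 14.3 CPM (SD, n = 3), Postn, periostin, rose 3.38-fold and Ccn2, a matricellular growth factor, 4.88-fold (edgeR adjusted p = 7.23e-25, 1.55e-24 and 6.54e-25). Col4a2 rose 3.82-fold. Col8a1, Timp3, Tagln, Col1a2 and Acta2 were the members that fell, Col8a1 2.86-fold and Timp3 1.85-fold, so that the contractile genes Tagln and Acta2 did not rise with the matrix genes. Markers of fibroblasts and fibro-adipogenic cells, which myoblast lines partly share, moved apart: of 6 tested, Ly6a (log2 fold change 0.59), Pdgfra (0.75), Dpt (2.09) and Pi16 (1.78) rose, and Cd34 (-0.26) and Dcn (-1.96) fell.

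**Figure D2:**
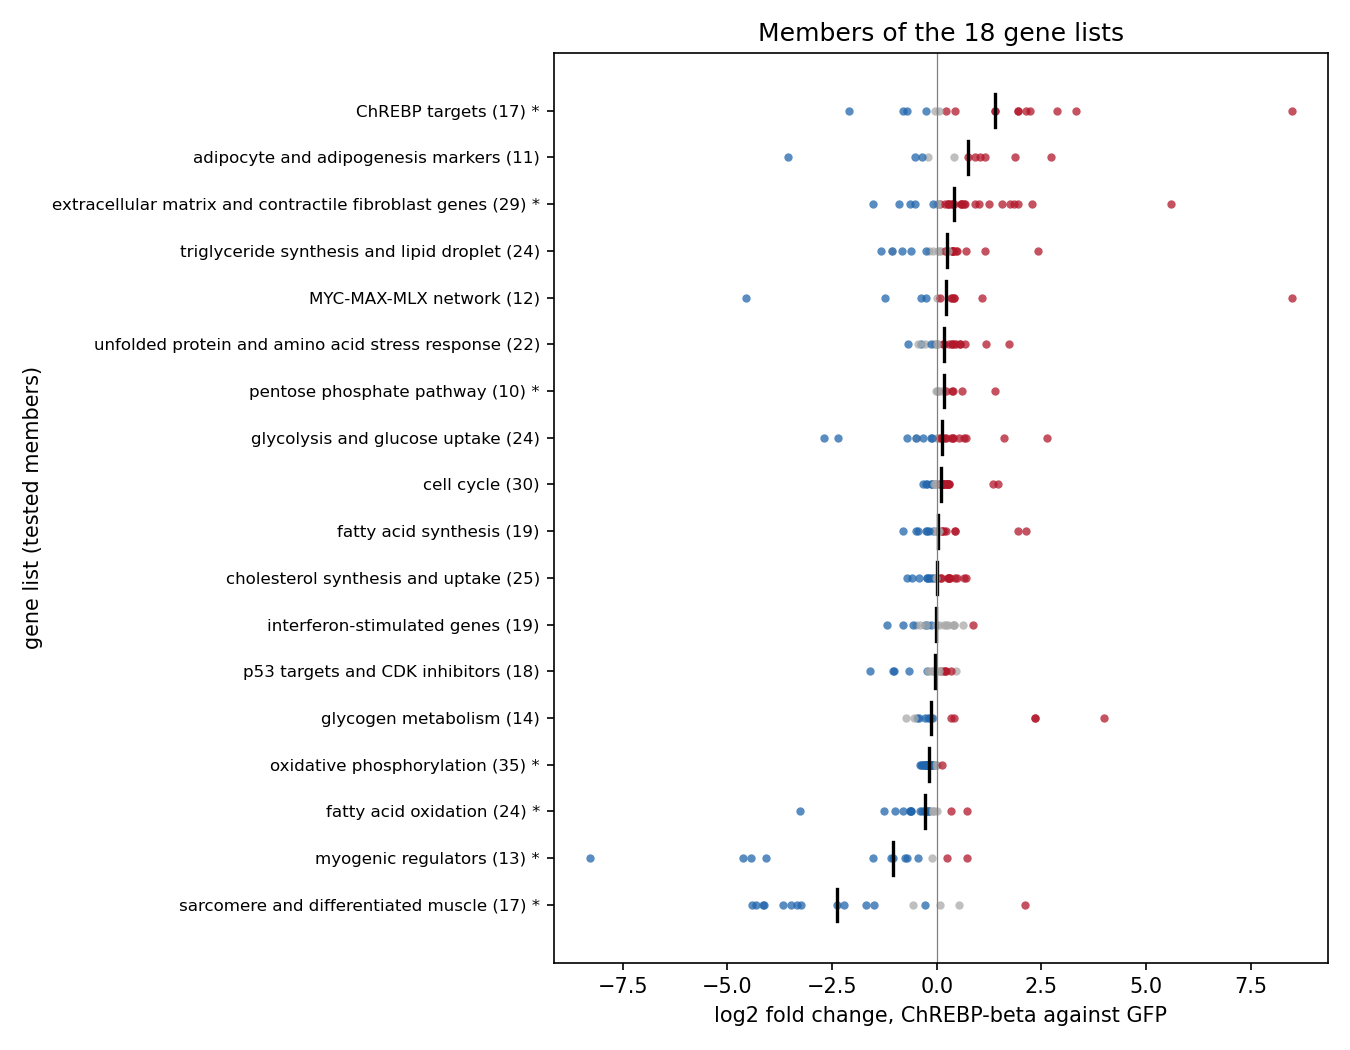
Log2 fold change with ChREBP-beta of each tested member of the 18 gene lists (x axis), with lists on the y axis ordered by their median (black bar) and the number of tested members in brackets. Red points were called higher, blue points lower and grey points not called by edgeR, and an asterisk marks the 7 lists called by camera with the preset correlation. List medians ran from -2.38 for sarcomere genes to 1.38 for ChREBP targets.

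The remaining lists were not called by camera. In the cell cycle list 17 of 30 members were higher, 5 lower and 8 not called (22 changed when adjusted over the list alone; camera adjusted p = 0.0810), led by Rrm2, a ribonucleotide reductase subunit, at 2.78-fold and Ccnd1, cyclin D1, at 2.54-fold (edgeR adjusted p = 2.95e-23 and 1.91e-22). All 6 libraries hold split reads at Ccnd1. The proliferation marker Mki67 was 1.06-fold higher and Cdk1 was not called. Stress response genes had 12 members higher, 3 lower and 7 not called (16 changed when adjusted over the list alone; camera adjusted p = 0.0810). The serine synthesis genes Psat1 and Phgdh rose 1.47-fold and 1.38-fold and Atf4, their regulator, 1.23-fold, whereas Ddit3 had a log2 fold change of -0.68. Without GFP replicate 1, the cell cycle and stress lists were called higher (camera adjusted p = 0.0266 and 0.0301). Cholesterol genes had 11 members higher, 8 lower and 6 not called (19 changed when adjusted over the list alone; camera adjusted p = 0.467), and Insig1 rose 1.58-fold. Among p53 targets 5 were higher, 5 lower and 8 not called (9 changed when adjusted over the list alone; camera adjusted p = 0.879), with Btg2 2.07-fold and Sesn1 1.59-fold lower and Phlda3 1.28-fold higher. Among interferon-stimulated genes 1 was higher, 6 were lower and 12 not called (6 changed when adjusted over the list alone; camera adjusted p = 0.492), with Ddx58 1.49-fold, Ifit2 1.21-fold and Ifih1 2.28-fold lower.

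In all, camera called 7 of the 18 lists, 3 higher and 4 lower, with its preset correlation of 0.01. None of the 18 was called by camera with the correlation estimated per list (lowest adjusted p = 0.122), under which 3 had an unadjusted p under 0.05. The self-contained test fry, which compares no list with other genes, called 18 of 18 for movement on balance in 1 direction. It also called 18 of 18 for change in either direction. Since edgeR called 58.7% of all tested genes, these fry calls do not set any list apart from other genes.

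Markers of cell types foreign to a myoblast culture were low, and several of them followed single libraries and not the groups. The hepatocyte marker Alb was read at 0.105, 0 and 16.3 CPM in GFP replicates 1 to 3 and at 14.9, 11.1 and 9.77 CPM in ChREBP-beta replicates 1 to 3 (edgeR adjusted p = 0.109). Lyz2, a macrophage marker also abundant in lung, was at 2.67 CPM in GFP replicate 1 and at 12.8 to 15.3 CPM in the 5 other libraries (edgeR adjusted p = 0.149). No hepatocyte or macrophage marker was called by the edgeR test of the report, but the call of some depended on the setting. With the replicate block, Alb and Fgb were called higher (edgeR adjusted p = 0.0318 and 0.0203), and limma-voom called Alb, Fgb and Lyz2 higher (adjusted p = 9.89e-05, 0.00123 and 0.028), as did edgeR without a filter (adjusted p = 2.14e-17, 0.00561 and 5.49e-05). Without GFP replicate 3, Alb and Fgb were called higher with log2 fold changes of 7.62 and 4.91, and Lyz2 with 0.89 (edgeR adjusted p = 1.89e-16, 4.79e-07 and 0.00403). Among endothelial markers Egfl7 was called, 1.59-fold higher (edgeR adjusted p = 0.0174), but not without ChREBP-beta replicate 2 (edgeR adjusted p = 0.0606). Among epithelial markers Krt19 was 2.43-fold lower, and Krt8 and Krt18 stood near 1 CPM in both groups. The lung gene Scgb1a1 had 3 counts in GFP replicate 1 and 642 to 1734 in each other library, and Sftpc, the surfactant gene of lung epithelium, had 5 against 349 to 489.

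**Figure D3:**
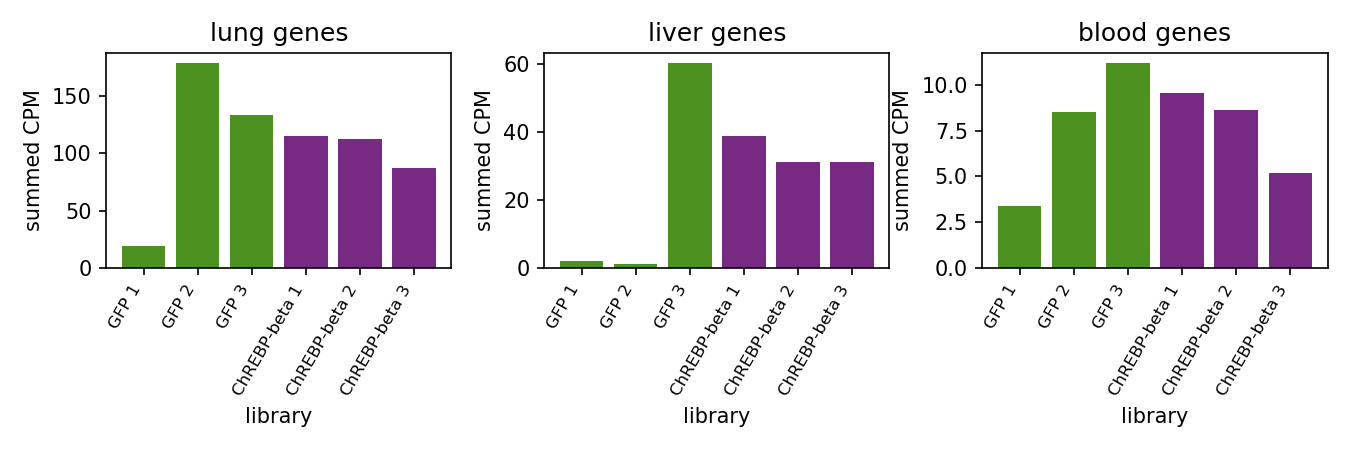
Summed CPM per library (bars; green GFP, purple ChREBP-beta) of genes typical of lung, liver and blood, lists written after the data were seen. Lung genes summed to 19.0 CPM in GFP replicate 1 and 87.5 to 179 CPM in the other libraries. Hopx, which did not follow this pattern, gave 288 of the 358 lung counts in GFP replicate 1. Liver genes summed to 2.02 and 1.18 CPM in GFP replicates 1 and 2 and 31.2 to 60.3 CPM in the other libraries.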

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

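Chosen only after the result was seen were the tests without carried lung, liver and blood genes, with length and GC offsets, and with Mlxipl left out of the lists. Mlxipl was called higher under every alternative run, with log2 fold changes from 8.40 to 8.65. Counts of genes ranged from 2989 to 3733 higher and from 3111 to 4166 lower, apart from the 2-fold minimum, under which 494 were higher and 903 lower because smaller changes are not counted. With each library left out in turn they ranged from 3287 to 3523 and from 3181 to 3324. The genes shared with the calls of the report had the same direction under every alternative. Library-size scaling moved the median of all genes by most, to -0.05. The difference in mitochondrial share ranged from -1.65 to -1.30 with each library left out.

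The replicate numbers did not pair the samples: 0 of 6 libraries correlated best with the library of their own number in the other group. With the replicate block, 3474 genes were higher and 3428 lower, and 6876 of the 6902 called genes were among the calls of the report.

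Of 324 alternative results for lists, 287 kept their direction and side of the threshold. Camera with the estimated correlation called 0 of 18 lists. Its adjusted p was 0.248 for ChREBP targets and for oxidative phosphorylation, and 0.122 for fatty acid oxidation and for sarcomere genes. It was 0.140 for myogenic regulators and 0.482 for the pentose phosphate pathway and the matrix list. The estimated correlation was 0.0016 for fatty acid oxidation and -0.042 for sarcomere genes, below the preset of 0.01. Their unadjusted camera p still rose, from 6.49e-05 to 0.0122 and from 9.27e-05 to 0.0136. A correlation above the preset is thus argued against as the cause for these lists. For the other lists called with the preset it ranged from 0.021 (myogenic) to 0.462 (matrix), and the cause was not tested. Since edgeR called 58.7% of all tested genes, a test without comparison to other genes says little about a single list. Fry, used here for movement on balance in 1 direction, is such a test and called 18. The 11 lists it added had fry adjusted p = 2.45e-05 for fatty acid synthesis and for adipocyte markers, 3.15e-05 for MYC-MAX-MLX, 8.99e-05 for glycogen, 2.18e-04 for glycolysis, 7.92e-04 for cell cycle, 8.99e-04 for triglyceride, 0.00390 for stress, 0.0196 for interferon, 0.0211 for cholesterol and 0.0243 for p53 genes. Nor was the cause of the changes that follow tested. Without a filter, camera called triglyceride (adjusted p = 0.0361), cell cycle and stress genes (both 0.0354). At a mean CPM of at least 5 it called triglyceride (0.0357) and glycolysis genes (0.0432) and not sarcomere genes (0.0629, with their median at -1.51 against -2.38). With each library left out, camera adjusted p ranged from 0.0435 (without GFP replicate 1) to 0.165 for triglyceride, from 0.0266 (without GFP replicate 1) to 0.122 for cell cycle, from 0.0301 (without GFP replicate 1) to 0.117 for stress and from 0.0162 to 0.0607 (without GFP replicate 3) for pentose phosphate genes. The direction of the glycogen list, never called by camera, reversed without a filter (adjusted p = 0.857), at a mean CPM of at least 5 (0.956), with the replicate block (0.949), with length and GC offsets (0.948) and without 4 of the 6 libraries (0.864 to 0.984 over all 6). The p53 list reversed at a mean CPM of at least 5 (0.956).

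Of 75 named genes besides Mlxipl, 67 kept direction and call under every alternative run. Genes that were never called by edgeR reversed. Cd14 was at 0.020 with length and GC offsets and ranged from -0.059 to 0.071 with each library left out. Cdh5 ranged from -0.032 to 0.79, Krt18 from -0.19 to 0.54 and Krt8 from -0.10 to 0.65. Alb, Fgb and Lyz2 became called without GFP replicate 3, with limma-voom and without a filter, and Alb and Fgb also with the replicate block (edgeR adjusted p = 0.0318 and 0.0203). The cause was not tested. Depth may limit Cdh5, Krt8 and Krt18, which lie near 1 CPM, since counting error at 1 CPM is 23.4% per library. Cdh5 spread by more than that, from 0.419 to 1.73 CPM with GFP and from 0.578 to 2.23 CPM with ChREBP-beta.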

Other observations

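Chosen only after the result was seen were the tests of repeat sequencing, of dilution and separate populations for the myogenic genes, of lung and liver RNA, and of expression of lung and liver genes under ChREBP-beta. The 6 further gene lists in the next paragraph were written after members of several were seen among the largest changes, so no list test is given for them.

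Of 8 neuromuscular junction genes tested, 7 were lower, none was higher and 1 was not called by edgeR. Lrp4, the agrin receptor, went from 123.5 to 6.80 CPM and Chrna1 from 35.5 to 2.70 CPM, while Chrnd and Chrng had no count with ChREBP-beta. In the insulin-like growth factor axis 8 of 13 were lower, 2 higher and 3 not called. Igfbp5 had a log2 fold change of -6.01, Igfbp3 of -5.21 and Igfbp2 of -3.51, and Igfbp7 rose by 0.77. Among semaphorins and their receptors 13 of 21 were lower, 6 higher and 2 not called, with Sema3c (4.51) and Sema7a (2.50) up and Sema3a (-4.71) and Sema3e (-4.26) down. Wnt ligands and modulators went both ways, with 6 of 22 higher and 12 lower: Dkk1, a Wnt antagonist, rose by 6.33, while Sfrp2 (-2.81) and the Wnt target Axin2 (-1.33) fell. Circadian clock genes (9 of 18 higher, 7 lower) and YAP and TEAD targets (6 of 20 higher, 10 lower) went both ways as well.

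The real grouping gave 7145 genes and 7 lists, and the highest of the other splits gave 0 genes by edgeR (43 to 92 at an unadjusted p under 0.05, against 7622 for the real grouping) and 6 lists by camera. Only 1 of the 10 splits, the real one, gave as many in each case, but 10 splits are too few for a share under 0.05. Each other split also put libraries of both groups on both sides, so the group difference entered the spread within sides. Few gene calls were therefore bound to follow, and part of the group difference stayed in the list tests. The splits thus cannot decide whether the calls arose by chance. Repeat sequencing of a single library per group is argued against by the spread between libraries. In every pair within a group, the median chi-square over genes was at least 1.90 times that expected from sampling. The spread does not tell separate cultures from separate libraries of the same culture. Split reads at near-identical genes do not explain why some ChREBP targets failed to rise, since 4 of the 6 targets not called higher (66.7%) hold none, while for Scd1 and Tkfc, which hold some, this stays open. The bound first written for this test asked that all 6 hold none, which was stricter than the explanation needs, since each target without split reads is a case it cannot cover; the looser bound was set after the values were seen.

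Myogenic genes were lower with ChREBP-beta. An admixture of cells lacking them would lower all members by about the fold of Myod1 (log2 fold change -4.64), but 9 of 13 members (69.2%) stayed above -2.32, the midpoint between that and no change, by over 2 SE. Cells that lack Myod1 yet keep other members stay open. Whether the GFP and ChREBP-beta cells were derived as separate populations that differed in myogenic state apart from the factor cannot be told apart from an effect of ChREBP-beta, since there is no second pair of populations, and the spread of 3.44% between libraries of a group does not speak to it. A lower myogenic state under ChREBP-beta is a candidate explanation.

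Oxidative phosphorylation genes were lower and extracellular matrix genes higher. Bias by transcript length and GC content is argued against: relative to other genes the lists stood at -0.18 (SE 0.015) and 0.45 (SE 0.036) before the correction and at -0.15 (SE 0.0089) and 0.49 (SE 0.038) after it, at least 12.9 SE from 0. RNA from lung is argued against as well, since without GFP replicate 1, which lacks most of it, at least 94.1% of each difference was left. For RNA from liver, which GFP replicate 2 lacks too, the 20 listed liver genes sum to at most 38.9 CPM in a ChREBP-beta library. That is 0.312% of the 12470 CPM by which the matrix genes called higher rose. It is 0.033% of the foreign RNA needed to dilute the oxidative phosphorylation genes. The listed genes are only a part of liver RNA, so the whole foreign share is larger by an unknown factor. Against GFP replicate 3 alone, which holds liver RNA, 93.1% of the oxidative phosphorylation and 95.7% of the matrix difference was left. These values argue against liver RNA, though no other GFP library holds it. A test of abundant transcripts in the scaling was void, since a scaling factor moves all genes of a library alike and 100% of the differences had to remain. A shift in expression under ChREBP-beta may explain the pattern but is confounded with any difference between the cell populations.

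Lung and liver transcripts were present in part of the libraries. Of 15 lung genes detected, 13 (86.7%) were lower in GFP replicate 1 than in each other library. Of 20 liver genes 18 (90%) were lower in GFP replicates 1 and 2 than in each other library. In GFP replicate 1, 3 lung genes (Hopx, Napsa and Cyp2f2), 0 liver genes and 1 of 4 detected blood genes reached 1 CPM. Hopx gave 288 of the 358 lung counts in GFP replicate 1. Hopx (288, 292 and 310 counts) and Napsa (24, 18 and 20) were even across GFP replicates 1 to 3, unlike the 13 other lung genes. Induction by ChREBP-beta is argued against, since in 91.4% of 35 genes a GFP library was as high as the lowest ChREBP-beta library. RNA or reads from lung and liver samples handled or sequenced alongside are a candidate source, and the step at which they entered cannot be read from these counts. Blood genes summed to 3.40 CPM in GFP replicate 1 and to 5.21 to 11.2 CPM in the other libraries.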
